A study of Mus musculus with 3 samples.

How the data were processed

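The files give, for each of the 3 libraries, every distinct insert sequence and its read count. Per the labels' protocols, total RNA from liver was extracted with the mirVana kit, RNAs of 18 to 30 nt were gel-purified, and libraries were built with a published small RNA protocol. The deposited counts are raw read counts, not normalised; adapter removal, any filter, an aligner and a genome build are not given in the sources used here. Inserts ran from 15 to 30 nt. The libraries carried no molecular identifiers in these files, so PCR copies count as separate reads and intervals and floors cover counting error only. Each group (mock, TuD-miR-122 and TuD-let-7) had 1 library; the number of animals behind it is not given in the sources used here.

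miRNAs were taken from the 1174 miRNA precursors of the GENCODE mouse annotation (release 21 for mouse, genome build GRCm38). That annotation gives no mature ends, so the 5′ end of each arm was set to the most frequent start of untailed reads on the precursor over the 3 libraries, for arms with at least 10 reads. The plan had assumed annotated 5′ ends. This gave 457 arms, which merged to 394 entries where the first 22 nt were identical. A read was assigned to an arm when it started at that 5′ end and matched the precursor for at least 16 nt without mismatch; the rest, up to 5 nt, was called a tail. A tail is therefore any 3′ end that does not match the precursor, base-call errors included. A read with a matching part under 21 nt was called trimmed, whether tailed or not. Reads that fitted several entries equally, 0.323% of miRNA reads, stayed out of single miRNAs and in the let-7 family sum. The family is let-7a, b, c, d, e, f, g, i and miR-98, guide strands. Near-identical miRNAs can exchange reads through sequencing errors, and such cases are named as uncertain. Names follow the annotation's symbols.

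Reads not assigned to a miRNA were compared with all annotated transcripts when 18 nt or longer. Reads that matched none made up 16.2% of mock, 20.6% of TuD-miR-122 and 23.2% of TuD-let-7; nuclear tRNAs and the long rRNA precursor are not in that annotation and fall there. Reads within the decoy hairpins and the vector's terminal repeat were counted by exact match. The hairpin sequences were written from the known TuD layout, with the site complementary to miR-122-5p or let-7a-5p and an insertion of 4 nt, and checked against the reads, which cover mainly the 5′ end.

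Values are RPM computed on the miRNA reads from neither miR-122 nor let-7 loci (1377687 in mock, 1452389 in TuD-miR-122 and 487673 in TuD-let-7), since the loss of an abundant target would raise the share of every other miRNA. In mock 1 read stands for less than in TuD-let-7, where the floor of 3 reads is 6.15 RPM against 2.18 in mock. Ratios carry an exact conditional-binomial interval and shares an exact Clopper-Pearson interval, both at 95%. No test between conditions was made. A non-target miRNA was counted as changed when it had at least 100 reads over both libraries and its interval lay wholly above 2 or below 0.5. For each list, the median log2 ratio (0.5 reads added, members with at least 20 reads) was placed among 10000 random lists matched in 5 bins of expression, as a description of these libraries. Differences in tailed or trimmed share were ranked among miRNAs with at least 1000 reads in both libraries.

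The text names, by a rule fixed before the data were examined, both miR-122 strands and the let-7 members; the 10 most abundant miRNAs of mock; per decoy, the 8 highest and 8 lowest non-target miRNAs past the 2-fold rule; the 3 largest rises and falls in tailing and in trimming; and up to 4 abundant members per list. The 14 lists cover the let-7 family, miRNAs co-transcribed with it, hepatocyte, immune, erythroid, endothelial, stellate and stromal, muscle and neural miRNAs, the miR-17-92, miR-29 and miR-30 families, a p53 and stress list, and the imprinted Dlk1-Dio3 cluster. Pancreas miRNAs, and the mRNAs of pancreas, muscle and liver, were listed after that.

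Alternatives chosen before the data were examined were other scalings (all reads, all miRNA reads, median-of-ratios size factors), the other decoy library as control, starts within 2 nt, matches of at least 18 nt, 1 internal mismatch, inserts read once left out, tails of at most 2 nt, trimming below 20 nt, tails of a single A left out, and minimums of 20 or 100 reads. The counting and list code was tested on simulated data made from the mock composition, with 60 miRNAs changed. For TuD-miR-122 against mock (217 miRNAs tested), 30 of 30 changed 3-fold and 30 of 30 changed 5-fold were recovered. For TuD-let-7 against mock (197 tested), 29 of 30 changed 3-fold and 30 of 30 changed 5-fold were recovered. Neither simulation gave a false call, but unchanged miRNAs differed there by counting error only, so this outcome was nearly fixed in advance. Differences between animals, tissue pieces or library preparations were not simulated. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.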

Results

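Small RNAs of 18 to 30 nt were sequenced from the livers of C57BL/6 mice, an inbred laboratory strain, 4 weeks after injection of scAAV9, a self-complementary adeno-associated virus vector. The vector carried no decoy (mock), a Tough Decoy (TuD) against miR-122, or a TuD against let-7. A TuD is a hairpin RNA, transcribed in the cell, that exposes binding sites for its target miRNA. Each group had 1 library, so no difference between groups has a replicate check, and every interval covers counting error only. The libraries held 3450317 reads (mock), 3681585 reads (TuD-miR-122) and 2066892 reads (TuD-let-7). Of these, 78.5%, 72.0% and 73.1% were assigned to miRNAs. The 10 most abundant miRNAs in mock were miR-122-5p, miR-21a-5p, miR-194-5p, let-7f-5p, miR-101b-3p, miR-192-5p, let-7a-5p, let-7g-5p, miR-29a-3p and miR-29b-3p. miR-122-5p alone made up 37.7% of the miRNA reads in mock, and miR-21a-5p 13.7%. Fragments of each decoy hairpin marked its library. Reads matching only the TuD-miR-122 hairpin numbered 491 in the TuD-miR-122 library and 0 in the others. Reads matching only the TuD-let-7 hairpin numbered 217 in the TuD-let-7 library, 11 in mock and 19 in TuD-miR-122. Of those 19 reads, 10 and 8 equal a fragment shared by both hairpins plus AA or A. They cannot be told apart from TuD-miR-122 hairpin fragments with added adenosines.

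The design asked what a decoy does to the stability and integrity of its miRNA. In the TuD-miR-122 library, miR-122-5p, the main miRNA of hepatocytes and a regulator of lipid metabolism, had a shorter matching part and more 3′ adenosines than in both libraries without that decoy. Reads with a 3′ tail that did not match the precursor made up 51.2% of miR-122-5p (exact Clopper-Pearson 95% interval 51.1 to 51.3), against 22.99% in mock (22.9 to 23.1) and 24.2% in TuD-let-7 (24.1 to 24.3). Reads whose matching part was under 21 nt, called trimmed here, made up 20.6% (20.5 to 20.7), against 3.08% in mock (3.04 to 3.11) and 3.04% in TuD-let-7 (3.01 to 3.08). Untailed reads of 21 nt or more made up 44.2% of miR-122-5p under the decoy, 75.8% in mock and 74.9% in TuD-let-7.

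Most of the added tails of miR-122-5p were of adenosine, with 25.4 of the 28.2 percentage points from tails of only A. Tails of only A stood on 41.6% of its reads in TuD-miR-122, 16.2% in mock and 17.9% in TuD-let-7. Tails of 2 to 5 A stood on 14.2%, 1.02% and 0.883% of reads in the same order, while tails of only T, which stand for uridine, stood on 1.18%, 3.06% and 2.37%. Tailing and trimming went together on the same molecules: of the reads whose matching part was 20 nt, 79.5% were tailed in TuD-miR-122 and 51.4% in mock, and of those with 21 matching nt, 59.0% and 15.9%. Set on the same scale, tails of 2 to 5 A were 11.2-fold (10.97 to 11.42) above mock, trimmed reads 5.38-fold (5.31 to 5.44) above mock, and the untailed 23-nt form 4.32-fold below mock.

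The miR-122-5p locus, Mir122 (ENSMUSG00000065402.1), lies on chromosome 18 from 65248861 to 65248926 of GRCm38, plus strand, in an exon of the long noncoding RNA AC157910.3. The first 22 nt of miR-122-5p, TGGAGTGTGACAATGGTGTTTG, span 65248866 to 65248887. Over all forms, its level in TuD-miR-122 was 594907 RPM (reads scaled to the non-target miRNA reads of the library), 0.803 of that in mock (95% counting interval 0.801 to 0.806). Against the TuD-let-7 library it was 0.297 (0.296 to 0.298), because that library, without a miR-122 decoy, held 2.70 times as much miR-122-5p as mock. Scaled to all reads, these values were 0.497 and 1.60. The ratio to mock lay within the spread of other miRNAs, as 59 of 228 non-target miRNAs had a lower one, and the size of any loss depended on the control library and the scale. Untailed reads of 21 nt or more were at 0.469 of mock and 0.175 of TuD-let-7. miR-122-3p, the passenger strand of the same precursor, was at 1.41 times mock (1.37 to 1.45) in TuD-miR-122 and 1.39 times mock (1.34 to 1.45) in TuD-let-7, but 0.823 of mock in TuD-let-7 when scaled to all reads. There were 82.7 reads of miR-122-5p per read of miR-122-3p in TuD-miR-122, 145 in mock and 281 in TuD-let-7.

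No non-target miRNA had a rise in tailing or trimming as large as that of miR-122-5p. Against mock, the tailed share of miR-122-5p was 28.2 percentage points higher and its trimmed share 17.5 points higher. Among the 74 non-target miRNAs with at least 1000 reads in both libraries, the median differences were -0.95 and -0.19 points. The largest rises in tailing were in miR-203-3p, a miRNA of skin and other epithelia (5.33 points), miR-19a-3p (5.16) and miR-19b-3p (4.82), both of the growth-promoting miR-17-92 cluster. The largest falls were in miR-23b-3p (-10.1 points), miR-486-5p, an erythroid miRNA that shares its sequence with miR-3107-5p (-8.67), and miR-92-3p (-6.56). For trimming, miR-223-3p, a myeloid miRNA (3.42 points), miR-24-3p (3.30) and miR-19a-3p (3.21) rose most, and miR-126a-5p, an endothelial miRNA (-11.1), miR-101a-3p (-7.91) and miR-365-3p (-3.96) fell most. The let-7 family, which this decoy does not target, had a tailed share 3.60 points below that of mock, 20.8% against 24.4%, and a level of 1.02 times mock (1.01 to 1.02).

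**Figure D1:**
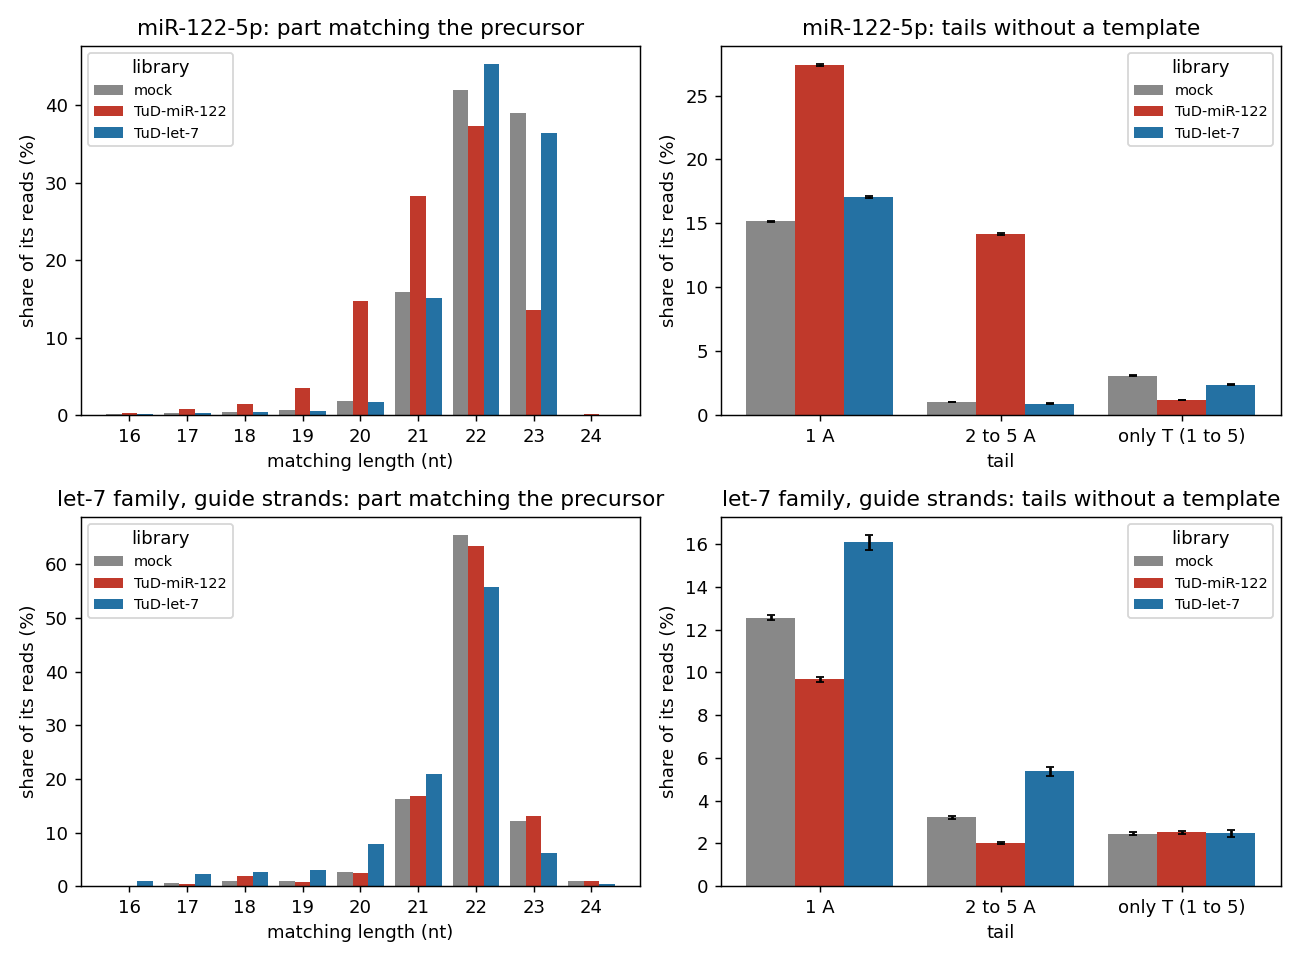
Isoforms of miR-122-5p (top) and of the let-7 family guide strands (bottom) in the 3 libraries: the length of the part that matches the precursor in nt (left), and the kind of 3′ tail (right), each as a share in percent of the reads of that miRNA or family, with exact 95% binomial intervals on the right. For miR-122-5p the TuD-miR-122 library stands apart, with 14.2% of reads ending in 2 to 5 A against 1.02% in mock, and for let-7 the TuD-let-7 library has the most reads with a matching part of 20 nt (7.90% against 2.74% in mock).

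In the TuD-let-7 library, the let-7 family, regulators of growth and differentiation genes, fell to 0.406 of mock (0.402 to 0.410), a 2.47-fold lower level. Against the TuD-miR-122 library, which has no let-7 decoy, it was 0.399 (0.395 to 0.403). Scaled to all reads, each ratio of TuD-let-7 to mock is 0.591 times the value given, so the family stood at 0.240 and every ratio between 1 and 1.69 turns to below 1. The members differed widely. let-7f-5p was 4.36-fold below mock and let-7a-5p 3.71-fold, while let-7b-5p was at 0.760 of mock (0.741 to 0.780) and let-7i-5p at 0.855 (0.827 to 0.884). Between these lay miR-98-5p (0.362), let-7d-5p (0.401), let-7g-5p (0.441), let-7c-5p (0.467) and let-7e-5p (0.654). With 1 mismatch allowed, miR-98-5p stood at 0.992 of mock (0.902 to 1.09) and let-7i-5p at 0.970 (0.939 to 1.003). The level of either thus depended on the matching rule. That setting can also move reads with a short matching part and a tail between members, such as from let-7a-5p to miR-98-5p. Whether the 0.992 holds such reads was not tested. With the mismatch, let-7f-5p (0.246) and let-7a-5p (0.292) stayed lowest. The passenger strands of the family, summed, were at 0.854 of mock (0.778 to 0.935), or 0.504 scaled to all reads, and there were 71.3 guide reads per passenger read in TuD-let-7, 150 in mock and 196 in TuD-miR-122.

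In the hairpin sequence assumed here, which the reads cover only at its 5′ end, the site of TuD-let-7 is complementary to let-7a-5p, TGAGGTAGTAGGTTGTATAGTT, apart from an insertion of 4 nt. Positions are counted from 1 at the 5′ end, with the base of let-7a first. let-7f-5p differs at G12A, let-7c-5p at A19G and let-7e-5p at T9G. let-7b-5p differs at A17G and A19G, let-7d-5p at T1A and T16C, let-7g-5p at G12T and T18C, and miR-98-5p at G11A and A19T. let-7i-5p differs at G12T, A17G, T18C and A19T. The genes lie at several loci of GRCm38. Mirlet7a-1, Mirlet7f-1 and Mirlet7d share chromosome 13, minus strand (48538179 to 48538272, 48537829 to 48537917 and 48536012 to 48536114), in exons of the long noncoding RNA 6720427I07Rik. Mirlet7i lies on chromosome 10 from 122985640 to 122985724, minus strand, in an exon of the pseudogene D630033A02Rik, and Mirlet7b on chromosome 15 from 85707319 to 85707403, plus strand, in an exon of Lncppara. Mirlet7g lies in an intron of Wdr82 on chromosome 9 from 106178840 to 106178927, plus strand. Mirlet7f-2 and Mir98 lie in introns of Huwe1 on chromosome X, from 151912346 to 151912428 and from 151913214 to 151913321.

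**Figure D2:**
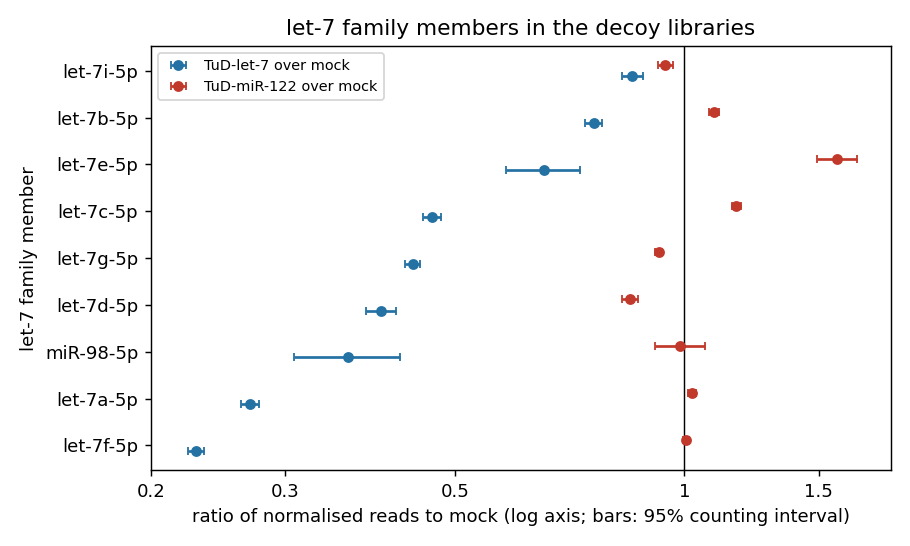
Level of each let-7 family member in the decoy libraries as a ratio to mock on a log axis, with 95% counting intervals as bars. In TuD-let-7 the 9 members run from 0.229 (let-7f-5p) to 0.855 (let-7i-5p), and in TuD-miR-122 from 0.848 (let-7d-5p) to 1.58 (let-7e-5p).

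The let-7 reads that remained in TuD-let-7 were shorter. Trimmed reads made up 16.8% of the family (16.5 to 17.2), against 5.20% in mock (5.12 to 5.28) and 5.59% in TuD-miR-122 (5.51 to 5.67). Tailed reads made up 34.0% (33.6 to 34.5), against 24.4% (24.3 to 24.6) and 20.8% (20.7 to 20.96). Tails of only A stood on 21.4% of family reads, against 15.8% in mock and 11.7% in TuD-miR-122. The untailed 23-nt form was 4.797-fold below mock, whereas trimmed reads stood at 1.31 times mock (1.28 to 1.35), or 0.776 of mock scaled to all reads. Members parted in tailing: the tailed share went from 17.3% in mock to 30.96% for let-7a-5p, from 15.3% to 29.8% for let-7f-5p and from 25.5% to 45.7% for let-7c-5p, but from 23.2% to 13.8% for let-7g-5p, from 49.8% to 40.5% for let-7b-5p and from 58.6% to 49.1% for let-7i-5p.

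Non-target miRNAs also had more tails and shorter matching parts in TuD-let-7 than in mock. Over 49 non-target miRNAs the median difference was 2.69 points for tailing and 2.73 for trimming; 8 of them exceeded the 9.61 points of the let-7 family in tailing and 3 exceeded its 11.6 points in trimming. The largest rises in tailing were in miR-126a-5p (14.8 points), miR-31-5p (14.2) and miR-140-3p (12.8), and in trimming in miR-146-5p, an immune miRNA (16.6), miR-26b-5p (13.1) and miR-93-5p (12.1). The largest falls were in miR-23b-3p (-5.77), miR-103-3p (-2.92) and miR-497-5p (-2.83) for tailing, and in miR-27b-3p (-4.99), miR-145a-5p (-4.72) and miR-23a-3p (-3.11) for trimming. This library held more mismatched reads: allowing 1 mismatch raised the non-target miRNA reads by 24.4% in TuD-let-7, 7.75% in mock and 8.51% in TuD-miR-122. The positions differed between miRNAs: set against exact reads plus those with that mismatch alone, position 11 of miR-21a-5p stood at 13.3% (mock 0.118%), its position 2 at 4.60% (mock 0.192%) and position 7 of miR-194-5p at 2.23% (mock 0.223%), with no position of miR-122-5p above 0.728%. With tails of at most 2 nt, 4 of 47 non-target miRNAs exceeded the let-7 family in tailing, and with 1 mismatch allowed 2 of 54 did, the largest rise being 23.8 points. With only tails of A counted, an alternative chosen after seeing the data, the median non-target difference was -0.11 points and none of the 49 exceeded the 5.67 points of the let-7 family.

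Outside the targets, 228 miRNAs had at least 100 reads over TuD-miR-122 and mock, and 79.8% of them lay within 2-fold. By the 2-fold rule, under which the 95% counting interval of the ratio must lie wholly above 2 or below 0.5, 31 were higher in TuD-miR-122 and 11 lower. Of the 31 higher miRNAs, 25 come from the imprinted Dlk1-Dio3 cluster on chromosome 12 (109585789 to 109743795 for the listed members), which is active in embryonic, neural and endocrine tissues and low in adult liver. The other 6 were miR-216a-5p, miR-216b-5p and miR-217-5p, known from the exocrine pancreas, miR-375-3p, known from pancreatic islets, and miR-200c-3p and miR-141-3p, known from epithelia. The 8 highest were miR-154-3p (31.3-fold, 11.9 to 117), miR-665-3p (31.1-fold), miR-379-3p (25.6-fold), miR-216b-5p (23.9-fold), miR-337-5p (21.5-fold), miR-136-3p (20.6-fold), miR-127-3p (19.1-fold, 15.7 to 23.3) and miR-216a-5p (18.8-fold, 13.5 to 26.9). Mock counts behind these ratios were low, from 4 reads for miR-154-3p to 108 for miR-127-3p.

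The lowest ratio in TuD-miR-122 was that of miR-378d-5p, called uncertain below, and the next lowest were those of skeletal muscle miRNAs. miR-133a-3p was 12.8-fold below mock, miR-133b-3p 12.2-fold and miR-1a-3p 10.7-fold, with 1090 reads of miR-1a-3p against 11080. miR-133b-3p is uncertain: only 116 of its reads over all libraries were untailed, while mock alone held 1061 reads. The start set here for miR-133a-3p lies inside that of the nearly identical miR-133b-3p. Reads of miR-133a with an earlier start could therefore be counted as tailed miR-133b-3p. miR-206-3p, specific to skeletal muscle, was at 0.156 of mock (0.127 to 0.191), and miR-133a-5p at 0.105 (0.0556 to 0.182). miR-802-3p was at 0.227 of mock (0.162 to 0.314), on 47 against 196 reads. The more abundant strand of the same precursor, miR-802-5p, was at 0.508 (0.467 to 0.553) and did not pass the rule. miR-378d-5p (0.0546) and miR-7j-5p (0.133) are uncertain, since their sequences are nearly those of the abundant miR-378a-3p and let-7i-5p; neither passed the rule with 1 mismatch allowed, at 0.728 and 0.765 of mock. Without the imprinted cluster, muscle and pancreas miRNAs, an alternative chosen after seeing the data, 2 miRNAs were higher and 6 lower.

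In TuD-let-7, 192 non-target miRNAs were tested against mock and 85.4% lay within 2-fold, with 7 higher and 8 lower. Of the 7 higher, 5 belong to the Dlk1-Dio3 cluster: miR-376a-3p (6.73-fold), miR-127-3p (5.75-fold), miR-134-5p (5.39-fold), miR-541-5p (3.33-fold) and miR-136-5p (3.26-fold). The others were miR-33-5p, which lies in an intron of the cholesterol regulator Srebf2 on chromosome 15 (2.83-fold, 2.27 to 3.51), and the uncertain miR-378d-5p (6.57-fold). Muscle miRNAs were lowest relative to mock. miR-1a-3p was 47.3-fold below mock (83 against 11080 reads), miR-133a-3p 34.5-fold, the uncertain miR-133b-3p at 0.0160 of mock (0.00585 to 0.0349) and miR-206-3p at 0.0166 (0.00451 to 0.0427). miR-133a-5p had 0 reads against 127, with an interval of the ratio from 0 to 0.0833. A floor of 3 reads in this library gave 14.99-fold lower, which goes beyond the bound of that interval. Also lower were miR-205-5p, an epithelial miRNA, at 3 reads against 155 (ratio 0.0547, 0.0112 to 0.163), miR-802-5p, a liver miRNA tied to glucose metabolism (0.178, 0.143 to 0.218), and miR-27a-3p, linked to lipid metabolism (0.422, 0.391 to 0.454). Scaled to all reads instead, the counts were 4 higher and 38 lower, because that scale moved the median of all non-target miRNAs by -0.76 on the log2 scale; miR-33-5p, miR-136-5p and miR-541-5p then no longer passed.

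**Figure D3:**
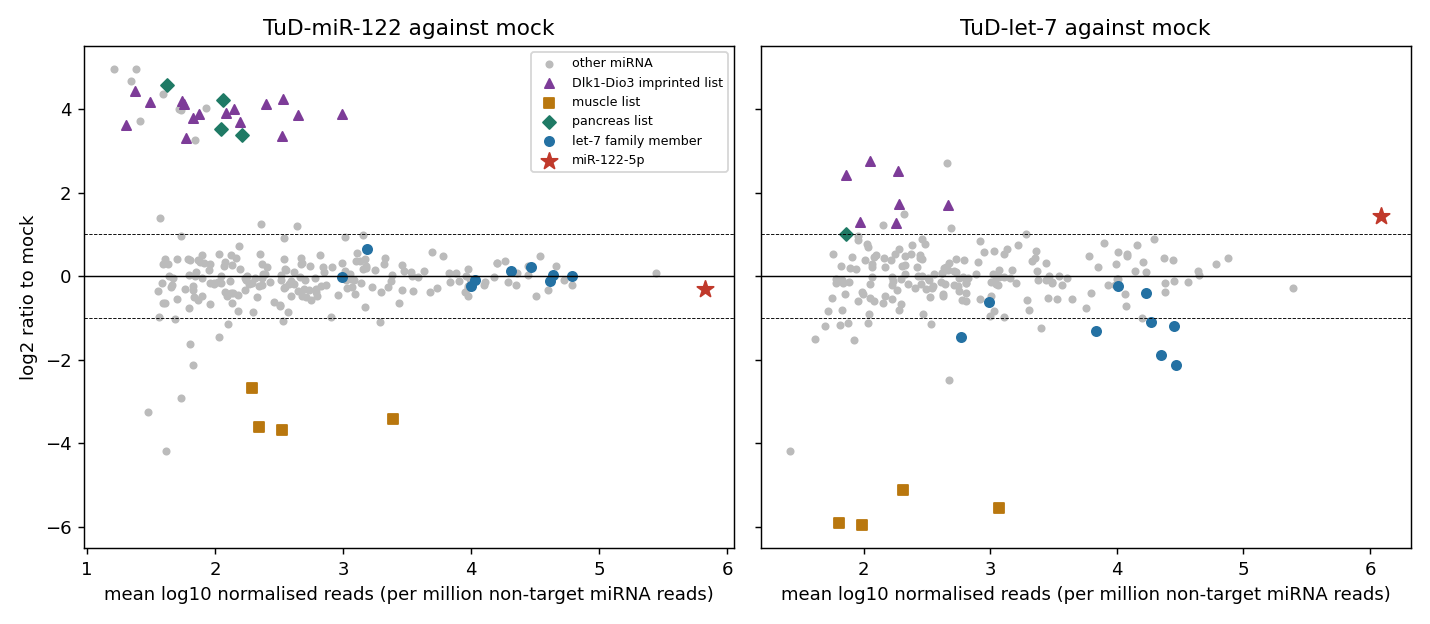
Ratio to mock (log2) of each miRNA with at least 100 reads over the library pair and reads in both, against its mean level (log10 of RPM on the non-target miRNA reads), in TuD-miR-122 (left) and TuD-let-7 (right); dashed lines mark 2-fold. Members of the muscle list lie among the lowest in both panels (list medians 10.7-fold and 47.0-fold below mock), with miR-378d-5p below them in TuD-miR-122. Members of the Dlk1-Dio3 list lie among the highest, with medians 14.0-fold and 2.83-fold above mock. Grey points near them include other strands from that cluster, and in TuD-miR-122 the pancreas miRNAs lie near them too.

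Of the 14 lists fixed before the data were examined, the muscle and Dlk1-Dio3 lists stood farthest from random lists of the same size and expression among those without a decoy target. All 26 measured Dlk1-Dio3 members were above mock in TuD-miR-122, with a median of 14.0-fold, above all 10000 random lists; their most abundant members were miR-136-5p (14.8-fold), miR-379-5p (14.6-fold), miR-127-3p and miR-541-5p (10.2-fold). In TuD-let-7 all 15 measured members were above mock, with a median of 2.83-fold. Both comparisons share the mock library; TuD-miR-122 against TuD-let-7 gave a median of 4.53-fold for the cluster and 4.39-fold for the muscle list. All 5 measured muscle members were below mock in both decoy libraries, though reads of the uncertain miR-133b-3p may be those of miR-133a. Erythroid miRNAs were above mock in TuD-miR-122 in 4 of 4 cases, with a median of 1.45-fold (percentile 99.2 among random lists), such as miR-451a-5p (1.39-fold) and miR-144-3p (1.501-fold), and at 0.790 in TuD-let-7 (percentile 10.2). The miR-17-92 list had a median of 0.797 in TuD-miR-122 (percentile 2.46, or 2.74 with at least 100 reads per member; miR-19b-3p 0.722, miR-92-3p 0.641) and 0.9996 in TuD-let-7. Immune miRNAs had a median of 0.708 in TuD-let-7 (percentile 2.09, or 4.91 with at least 100 reads per member) and 1.04 in TuD-miR-122. In TuD-let-7, 0 of 8 were above mock, such as miR-142-3p (0.752) and miR-223-3p (0.561). That count includes miR-146-5p at 0.999 (0.945 to 1.06), or 1.003 with 1 mismatch allowed.

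The other lists lay between the 2.5th and 97.5th percentile against mock. Hepatocyte miRNAs had a median of 0.865 in TuD-miR-122 and 1.31 in TuD-let-7 (percentile 95.9; 0.773 scaled to all reads), with miR-194-5p at 0.865 and 1.35 and miR-192-5p at 0.8002 and 1.02. miRNAs made from the same transcripts as let-7 had medians of 1.04 and 1.30 (0.769 in TuD-let-7 scaled to all reads), with miR-125b-5p at 1.45 (0.859) and miR-99a-5p at 1.49 (0.879) of mock in TuD-let-7. The medians were 1.16 and 0.7999 for endothelial miRNAs (miR-126a-3p at 1.28 and 1.08), 1.07 and 0.930 for stellate and stromal miRNAs (miR-143-3p at 1.24 and 1.26), and 0.916 and 1.10 (0.648 scaled to all reads) for the miR-30 family (miR-30a-5p at 0.909 and 1.34). They were 1.18 and 0.908 for the miR-29 family (miR-29a-3p at 1.18 and 1.09) and 0.944 and 1.03 (0.609 scaled to all reads) for the p53 and stress list (miR-21a-5p at 1.05 and 0.828, or 0.867 in TuD-let-7 with 1 mismatch allowed). The neural list had a single measured member, miR-9-5p, with 17 reads in TuD-miR-122, 5 in TuD-let-7 and 15 in mock. The let-7 family list itself had a median of 1.01 in TuD-miR-122 and 0.441 in TuD-let-7, below all random lists.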

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

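The decoys themselves left signal outside the miRNA comparisons. Reads that matched the TuD-miR-122 hairpin and not the TuD-let-7 hairpin numbered 491 in the TuD-miR-122 library and 0 in mock. Reads that matched the TuD-let-7 hairpin alone numbered 217 in the TuD-let-7 library and 11 in mock, or 105 against 3.19 RPM on all reads. Most began at the first base of the hairpin; the most frequent was GACGGCGCTAGGATCATCAACC, with 186 reads in TuD-miR-122.

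The tests of 3 patterns follow; those on miR-217-5p and miR-375-3p, on the sum of the pancreas miRNAs and on mRNA fragments were set before their values were seen, and the others after, with the scale of the non-target median revised later still.

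The imprinted Dlk1-Dio3 miRNAs stood far above mock in the TuD-miR-122 library. A general rise of all other miRNAs after the loss of miR-122 reads is argued against by the median non-target ratio of 1.07 when all miRNA reads, targets included, set the scale. Pancreas in the dissected tissue is a candidate source: miR-375-3p was 10.4-fold above mock (8.10 to 13.4) and miR-217-5p 11.5-fold (8.45 to 15.9). The genes of miR-217, miR-216a and miR-216b lie close together on chromosome 11, plus strand. miR-217-5p could therefore follow miR-216a-5p and miR-216b-5p, already known to be high, from any origin, and is no separate test. Fragments of 21 pancreas mRNAs, set against those of 16 liver mRNAs, were 8.67-fold above mock (4.28 to 20.5, on 134 against 8 reads). Pnlip (25 reads), Ctrb1 (20) and Cel (17) led, with 0 reads for Ins1, Ins2 and Gcg. The cluster rose from 861 to 12559 RPM and the 4 pancreas miRNAs from 119 to 1613. TuD-miR-122 exceeded TuD-let-7 by 4.53-fold in the cluster's median. In that comparison miR-216b-5p was 25.4-fold, miR-216a-5p 17.6-fold, miR-217-5p 16.6-fold and miR-375-3p 5.13-fold higher. Pancreas mRNA fragments were only 1.44-fold higher there (0.856 to 2.60), on 16 reads in TuD-let-7. These values disagree, so whether the cluster's rise has that source stays open, as does an effect of the decoy or a difference between animals. In TuD-let-7 pancreas as the whole source is argued against by the sum of the 4 pancreas miRNAs, none of them abundant in liver, at 1.36 times mock (1.03 to 1.79), below the bound set beforehand, the cluster's median of 2.83, but a part from pancreas stays open on values that disagree: miR-375-3p, of islets, was at 2.02 (1.37 to 2.94) with 0 reads for Ins1, Ins2, Gcg and Iapp, whereas acinar miRNAs were at 0.691 to 1.07 but pancreas mRNA fragments, such as Ctrb1 (4 reads), 6.01-fold above mock (2.43 to 16.2) on 16 reads.

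Muscle miRNAs were highest in the mock library. The other libraries held at most 0.0922 of its miR-1a-3p in RPM on all reads (0.0866 to 0.0981), which restates the pattern and is no separate test of carry-over. Muscle in the dissected tissue is a hypothesis that stays open: miR-133a-3p per miR-1a-3p in mock was 1.20 times that in TuD-miR-122 (1.01 to 1.44), but their genes lie side by side, so other origins would also keep that proportion. Fragments of muscle mRNAs, 8 reads in mock and 5 in TuD-miR-122, gave a ratio of 3.09 (0.892 to 12.01), too few to decide. An effect of the decoys on muscle miRNAs in liver was not tested, since each group has 1 library.

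The let-7 members fell unequally in the TuD-let-7 library. Base-call errors at position 11 are argued against as the whole reason: with 1 mismatch allowed, the ratio to mock of let-7i-5p was still 3.95 times that of let-7f-5p. With that setting miR-98-5p went from 0.362 to 0.992 and let-7i-5p from 0.855 to 0.970, so neither is a firm fall. The setting can also move trimmed, tailed reads between members, so the 0.992 may hold reads of other members. The correlations with 1 mismatch allowed, given below, include that value. A hypothesis is that members closer to the decoy's let-7a site fall more. Over 9 members, the number of differences from let-7a-5p against the log2 ratio gave Spearman's rho of 0.532 (exact one-sided permutation p = 0.0710) and Pearson's r of 0.645 (exact one-sided permutation p = 0.0294), and without let-7a-5p and let-7i-5p r was 0.177. With 1 mismatch allowed rho was 0.674 (exact one-sided permutation p = 0.0262) and r 0.680 (exact one-sided permutation p = 0.0155), or 0.481 without those members, but the members are not independent, let-7e-5p with 1 difference kept 0.654 of mock, and the hypothesis stays open.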

How the results depend on the processing

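No paired analysis was possible because each group has 1 library. Counting A-only tails, scaling further TuD-let-7 ratios to all reads, miR-21a-5p with 1 mismatch, untailed reads or the counts without cluster, muscle and pancreas miRNAs was chosen after seeing the data, and the cluster was redefined by its position, in place of list names, after a first count had been seen. No abundance of a target in its own decoy library and no share reversed. Counts were judged by size only, so a reversal was not defined for them. The cause of each shift below was not tested unless it follows from the alternative itself. miR-122-5p in TuD-miR-122 against mock (0.803) became 0.794 per all reads, 0.865 per all miRNA reads, 0.843 with median-of-ratios factors, 0.297 against TuD-let-7, 0.801 with starts within 2 nt, 0.798 with an 18-nt match, 0.794 with 1 mismatch and 0.469 for untailed reads. The let-7 family in TuD-let-7 (0.406) became, in that order, 0.240, 0.257, 0.398, 0.399 against TuD-miR-122, 0.4005, 0.397, 0.435 and 0.344. The miR-122-5p tailed share (51.2%) became 50.7% with an 18-nt match, 47.5% with tails of at most 2 nt, 23.8% without single-A tails (mock 7.84%) and 41.6% with A-only tails. Its trimmed share (20.6%) became 21.01% with starts within 2 nt, 19.8% with an 18-nt match, 19.2% with short tails and 5.89% below 20 nt (mock 1.31%). The let-7 tailed share (34.0%) became 31.9% with an 18-nt match, 31.3% with 1 mismatch, 33.3% without inserts read once, 29.2% with short tails, 18.0% without single-A tails (mock 11.9%) and 21.4% with A-only tails. Its trimmed share (16.8%) became 14.1%, 15.5%, 16.2% and 11.8% under the first 4 of these and 8.91% below 20 nt (mock 2.46%).

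The 42 non-target miRNAs past 2-fold in TuD-miR-122 became 64 with at least 20 reads, 52 of them higher, and 8 without the imprinted cluster, muscle and pancreas miRNAs. The 15 in TuD-let-7 became 42 per all reads, 38 lower, 38 per all miRNA reads, 34 lower, and 5 without those miRNAs. Those scalings moved the non-target median by -0.76 and -0.66 (log2) in TuD-let-7, and by -0.02 and 0.11 in TuD-miR-122. Of the list medians against mock, 8 lay outside the 2.5th to 97.5th percentile, and 6 with at least 100 reads per member, without the immune list in TuD-let-7 (-0.49, percentile 4.91) and miR-17-92 in TuD-miR-122 (-0.33, percentile 2.74). For the miRNAs named as highest or lowest, 209 of 217 values under the alternatives stayed past the rule. Scaled to all reads, further ratios of TuD-let-7 to mock turned to below 1: miR-122-3p 0.823, let-7 trimmed reads 0.776, miR-125b-5p 0.859, miR-99a-5p 0.879, miR-194-5p 0.797, miR-192-5p 0.604, miR-126a-3p 0.636, miR-143-3p 0.743, miR-30a-5p 0.794 and miR-29a-3p 0.641, with the list medians of hepatocyte (0.773), let-7 co-transcribed (0.769), miR-30 (0.648), p53 and stress (0.609) and neural miRNAs (0.592). Which scale is right for that library was not settled. Depth limits TuD-let-7 most, with 487673 non-target reads.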

Other observations

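Both strands of the precursors could be compared within each library, a ratio that no scaling between libraries affects. The tests of this ratio were chosen after the values had been seen, and their bound was later widened by the difference between the libraries without the decoy. A lower production of the miR-122 precursor would lower both strands, yet miR-122-5p had 82.7 reads per read of miR-122-3p in TuD-miR-122 (81.1 to 84.3), below 145 in mock (142 to 148) and 281 in TuD-let-7 (272 to 291). For the let-7 family the ratio was 71.3 in TuD-let-7 (65.8 to 77.4), below 150 in mock (144 to 157) and 196 in TuD-miR-122 (186 to 205). For miR-122 the ratio was 1.75-fold below that of mock, less than the 1.94-fold between mock and TuD-let-7, which both lack its decoy, so lower production cannot be told apart from later loss. For let-7 it was 2.10-fold below that of mock, more than the 1.30-fold between the libraries without its decoy, so the bound was passed. That bound leaves out the TuD-let-7 library itself, where the ratio of miR-122, not a target there, differed from mock by 1.94-fold. The let-7 sum also mixes members: let-7d-3p gave 939 of the 2002 passenger reads in mock, but let-7d-5p 14931 of the 300471 guide reads. Lower production of let-7 therefore cannot be told apart from later loss either. The 1.30-fold rests on 1 pair of libraries.

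Reads of 15 to 17 nt, below the gel-purified range, made up 1.29% of TuD-miR-122, 0.457% of mock and 0.338% of TuD-let-7. Mitochondrial RNA fragments made up 0.613%, 0.289% and 0.139% in the same order. Reads within the terminal repeat of the vector numbered 51 in mock, 22 in TuD-miR-122 and 6 in TuD-let-7.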
